A study of Mus musculus with 6 samples.

How the data were processed

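Single cells from 6 subcutaneous tumours in 129SV mice were profiled with 10x Genomics 3′ chemistry (v2). The tumours grew from LKR13, a murine lung adenocarcinoma line with mutant Kras. LKR13K is the line itself, LKR13KK also lacks KEAP1, and LKR13KLK lacks both KEAP1 and LKB1 (encoded by Stk11). There were 2 untreated tumours per group, dissociated with enzymes, strained and freed of red cells with ammonium chloride per the labels. The submitters' processing notes name Cell Ranger, with no version, Seurat 3.1.5 and mm10, and the series text says that the processed table was corrected after release.

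The deposited table is titled as normalized, but every value in it was a whole number of at least 0, so the values were treated as raw UMI counts (unique molecules per gene and cell). It held 22497 gene symbols and 7956 cells with 54817583 UMIs, and 3255 symbols had no UMI. The deposited cells had been filtered: the lowest total was 500 UMIs, the fewest genes 201 and the highest mitochondrial percentage 14.9. Cells were assigned to tumours by the ends of their column names.

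LKR13K 2 carried other gene symbols than the remaining tumours. In it alone, 200 symbols that the other tumours expressed stood at 0 (at least 10 UMIs would have been due), and 362 symbols with at least 10 UMIs occurred only there. Among these, 123 unambiguous pairs of an old and a new name of 1 gene in RefSeq were merged. The other 316 symbols were left out in all tumours, Mx1 and Ido2 among them, which removed 0.444% of the UMIs of LKR13K 2 and 0.0752% to 0.0978% of those of the others. The genes left numbered 22058.

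Counts were scaled to 10000 per cell and log-transformed. Variable segments of antigen receptors were kept out of the choice of 2000 variable genes, 30 principal components and a graph of 20 shared nearest neighbours were computed, and Leiden clustering at resolution 1 gave 21 clusters. A cluster was named from cell type markers when at least 3 markers were found in at least 25% of its cells and lay more than 1 log2 unit over the median cluster, with 0.1 per 10000 added. The 10 leading genes of each cluster were compared with the markers of other classes, and none held more markers of another class than of its own. Every class name below therefore means a cluster that resembles that cell type by these markers. Among its leading 10 genes the conventional dendritic cluster had 0 of its own markers. The natural killer (NK) cluster, 2 phagocyte clusters and 1 T cell cluster had 1, and the pericyte cluster had 1 beside 1 of another class, so these names are less certain. T and NK cells were clustered again with 1500 genes and 20 components, giving 12 subclusters. CD8 subclusters 8 and 11 had 0 of their own markers among the leading 10, and subcluster 6 had 1 beside 1 of another subset. No doublet caller was run. As an alternative, cells with at least 2 markers of another class were left out, which removed 46.8% of all cells and 64.4% of fibroblasts, far more than doublets alone would give.

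Shares of the 12 classes per tumour were compared with limma 3.58.1 on the logit scale with 0.5 cells added, all 6 tumours sharing 1 estimate of spread, and p was adjusted by Benjamini-Hochberg over 36 tests. Subsets of T and NK cells were tested the same way over 15 tests. An exact permutation test of 2 tumours against 2 cannot go below p = 0.3333, two-sided. Intervals of single shares are Wilson 95% intervals, and a count of 0 was given an upper limit of 3 cells of the total. Intervals and limits cover counting error only.

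For genes, UMIs were summed per tumour and class. Limma on averaged log-normalised values had been chosen before the data were examined, along with the comparisons, the gene lists, the markers and the rule for named genes. Since the table held counts, edgeR 4.0.16 took its place as the main test (TMM factors, quasi-likelihood F test, two-sided, Benjamini-Hochberg within each class and comparison, adjusted p under 0.05), and the limma test was kept as an alternative. Genes needed a mean of 25 CPM (UMI counts scaled to a common total per tumour and class) over the 6 tumours. The planned rule of at least 50 cells in every tumour left 2 classes, mononuclear phagocytes and fibroblasts. T cells and neutrophils were added after the data were seen, with at least 20 cells in every tumour. Named genes were the 10 largest changes in each direction that passed with no overlap between tumours, or the 5 with the smallest p where fewer than 5 passed. Genes of ribosomal proteins, predicted genes and sex-linked genes were counted and not named. A fold against a group at 0 was computed against 3 UMIs over that group.

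The gene lists numbered 21, with 18 further lists of cell type markers, and 28 of these had at least 3 genes measured in some class, 7 of them marker lists. They were tested with camera in limma at a preset inter-gene correlation of 0.01, and again with the correlation estimated. Adjustment was over 228 tests of list, class and comparison. The estimated form rests on the few degrees of freedom that 6 tumours in 3 groups leave, so hardly any list could pass it. Members passing when p was adjusted over the list alone were counted too.

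Alternatives covered the denominator, clustering resolution, scale, replicate block, leaving out each tumour, fitting 2 groups only, pseudocounts of 1, 5 and 20 in limma, filters of 0 and 100 CPM, averages of log values, median centring, quantile normalization, limma without a trend, robust empirical Bayes and the doublet-marker rule. DESeq2 1.42.0 and further settings were added after the data were seen. The gene test was tested on simulated data, in which 200 genes of each class were changed by 2, 4 or 8 times and a list of 20 genes by 1.5 times. Positions are those of GENCODE M21 (GRCm38). Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3 were used.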

Results

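Keap1 and Stk11 were read first, since the knockouts targeted them in the injected line. The series describes non-malignant cells, and no cluster was named epithelial. Per tumour, the epithelial marker Epcam was between 0.695 and 17.3 CPM (UMI counts scaled to a common total), Krt8 between 19.7 and 50.8 and Krt18 between 29.2 and 79.0. Whether malignant cells were among those read was not settled, so the values below check neither knockout. Keap1 (9:21229730–21239361) was at 26.8 and 30.8 CPM in the LKR13K tumours, 28.5 and 27.2 in LKR13KK, and 26.1 and 23.6 in LKR13KLK. Stk11 (10:80115803–80130682) was at 61.0 and 70.4 CPM in LKR13K, 54.5 and 55.6 in LKR13KK, and 52.2 and 48.0 in LKR13KLK. Neither gene passed in any class in which it was tested.

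The table described 7956 cells from 6 tumours in 3 groups of 2. LKR13K 1 and 2 gave 1767 and 1323 cells with 11775887 and 6979241 UMIs. LKR13KK 1 and 2 gave 2172 and 681 cells with 16023244 and 4192839 UMIs. LKR13KLK 1 and 2 gave 1232 and 781 cells with 11526833 and 4319539 UMIs. Median UMIs per cell ranged from 3561 to 6522. UMIs per tumour ranged from 1215133 to 6184553 in mononuclear phagocytes, 1505180 to 5549518 in fibroblasts, 90764 to 4181315 in T cells and 47372 to 321677 in neutrophils. LKR13KK 2 and LKR13KLK 2 held only 40 and 39 T cells, and LKR13KK 2 held 47 neutrophils, so those profiles were the thinnest. Values are means ± SD of 2 tumours, and errors of log2 changes are standard errors. If no gene differed, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. The counts at that limit given below lay under this share in all phagocyte comparisons. The same held in fibroblasts and T cells of LKR13KLK against LKR13KK and in neutrophils of LKR13KK against LKR13K. Furthest above this share lay fibroblasts of LKR13KLK against LKR13K.

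The first comparison, LKR13KK against LKR13K, asked how the cells read differ in tumours that lack KEAP1. Plasma cells, the antibody secretors, made up 2.57% ± 1.49 of cells in LKR13K tumours and 0.0691% ± 0.0977 in LKR13KK, and their odds fell 22.4-fold (limma adjusted p = 0.00301). T cells stood at 34.9% ± 5.99 against 10.3% ± 6.33, apart in every tumour but not past the threshold (adjusted p = 0.0715). B cells (4.42% ± 4.64 against 0.322% ± 0.456) and conventional dendritic cells (2.61% ± 0.804 against 0.469% ± 0.248), which present antigen, both had adjusted p = 0.0514. Mononuclear phagocytes were 30.6% ± 8.01 against 51.3% ± 3.43 (adjusted p = 0.254) and fibroblasts 7.30% ± 2.08 against 17.7% ± 5.09 (adjusted p = 0.186). Mast cells or basophils, neutrophils, NK cells, plasmacytoid dendritic cells, endothelial cells and pericytes had adjusted p between 0.186 and 0.990. The plasma cell call ended without LKR13K 1 (adjusted p = 0.125) and without LKR13KK 2 (0.0522), and on the arcsine scale. The B cell share passed without LKR13K 2, LKR13KK 1, LKR13KLK 1 or LKR13KLK 2. Without LKR13KK 1 its group was LKR13KK 2 alone, which held 0 B cells of 681. LKR13KK 2 held 0 of 681 plasma cells, which allows a share of up to 0.441%.

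**Figure D1:**
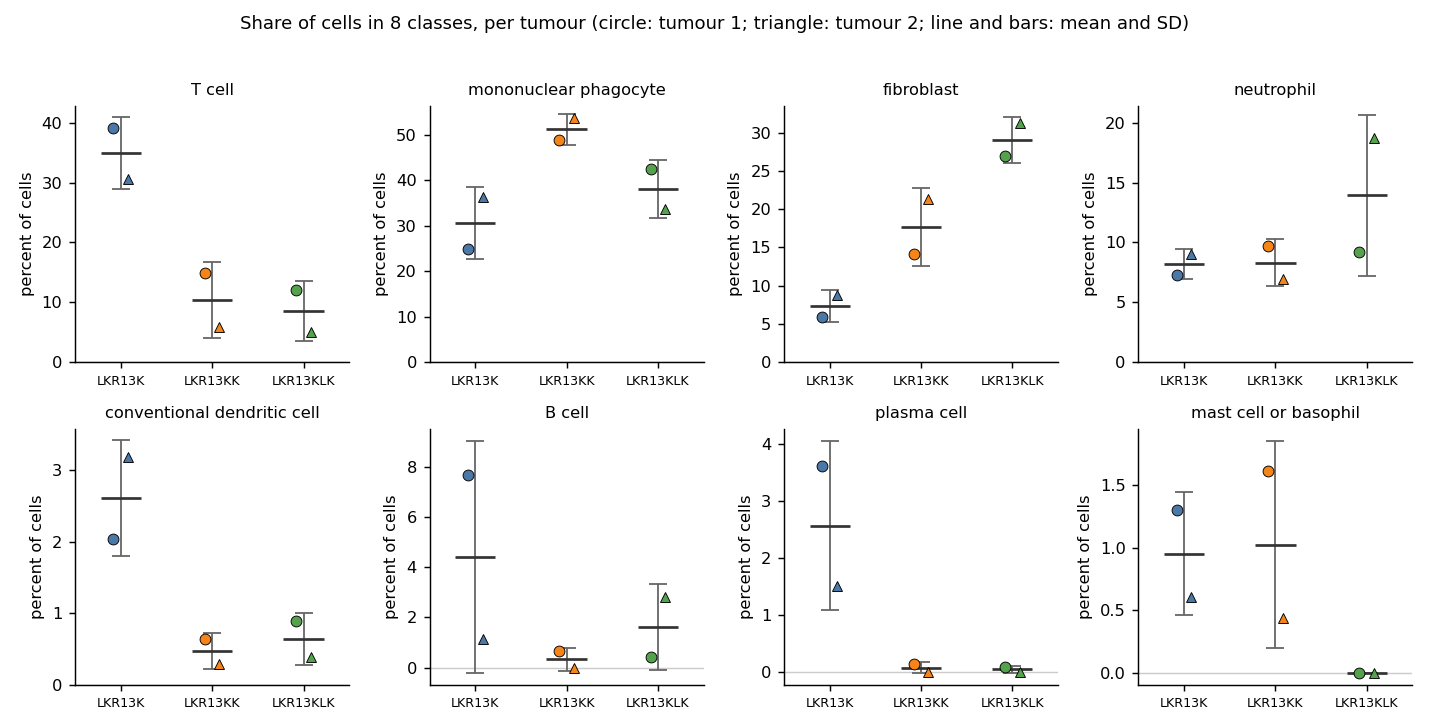
Share of all cells, in percent, for 8 cell classes in each tumour of the 3 groups, with the mean and SD of 2 tumours. Both LKR13K tumours lie above all other tumours for T cells and plasma cells, and mast cells or basophils were counted in no LKR13KLK tumour.

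In LKR13KK fibroblasts, edgeR passed 0 of 4520 genes against LKR13K, with 273 at an unadjusted p under 0.05 and 25 by DESeq2. The smallest p belonged to Gzme (14:56117626–56120625), a serine protease known from cytotoxic cells, at 64.2 ± 6.17 against 12.3 ± 2.26 CPM (log2 change 2.45 ± 0.23, adjusted p = 0.0590). Ifitm1 (7:140967221–140969825), an interferon-inducible membrane protein, was at 147 ± 34.1 against 32.5 ± 10.1 CPM (adjusted p = 0.0705). Col8a1 (16:57624258–57754737), a short-chain collagen, was at 244 ± 34.3 against 718 ± 51.2 CPM (log2 change −1.51 ± 0.17, adjusted p = 0.0698). Moxd1 had a log2 change of 1.79 ± 0.25 (adjusted p = 0.150). Igkc, the kappa antibody chain, was 0 in LKR13KK fibroblasts (adjusted p = 0.0590), and 902 of its 914 UMIs in LKR13K lay in 2 cells. DESeq2 passed Gzme, Ifitm1, Col8a1 and Moxd1 (adjusted p = 1.40e-09, 1.40e-09, 1.10e-09 and 6.88e-05) but not Igkc (0.580). Without LKR13K 1, LKR13K 2 or LKR13KLK 2 edgeR passed 12, 6 and 1 genes.

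As groups in LKR13KK fibroblasts, 3 lists moved at the preset correlation. Values after "without" are adjusted p once that tumour was left out. Glycolysis and hypoxia genes rose (17 of 21 above 0, median log2 change 0.36, adjusted p = 0.00167), with Mif at 0.67, Aldoa at 0.62 and Pgk1 at 0.35. That call ended without LKR13K 2 (0.0602) and turned its direction without LKR13KK 1 (0.942). Immediate early and heat shock genes of dissociation stress fell (3 of 15 above 0, median −0.58, adjusted p = 0.00465), and the call ended without LKR13K 1 (0.967). Ribosomal protein genes, read as a sign of RNA quality, rose by a median of 0.20 (65 of 81 above 0, adjusted p = 0.000983), and the call ended without LKR13K 2 (0.139). No member passed over all genes or adjusted over the list alone, and these lists had adjusted p between 0.920 and 0.947 with an estimated correlation.

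LKR13KK T cells showed higher proliferation genes as a group (15 of 16 above 0, median log2 change 0.64, adjusted p = 4.45e-06). Its members included the kinetochore gene Cenpf (1.77 ± 0.54), the survivin gene Birc5 (1.38), the topoisomerase Top2a (1.07) and the replication clamp Pcna (−0.83). Genes of glycolysis and hypoxia rose too (15 of 16 above 0, median 0.39, adjusted p = 0.000983), with Tpi1 at 1.02 and Pgam1 at 0.94, until LKR13KK 1 was left out (0.0690). Targets of NRF2, the factor that KEAP1 restrains, rose by a median of 0.25 (10 of 11 above 0, adjusted p = 0.0392), and the call ended without LKR13K 1 (0.114) or LKR13KK 1 (0.156). No member of the 3 lists passed over all genes or adjusted over the list alone, and each list had adjusted p = 0.920 with an estimated correlation. Among T and NK cells, subcluster 8, with Birc5 and Mki67 among its leading genes, held 35 of 765 and 24 of 435 cells in LKR13K. It held 32 of 389 and 6 of 47 in LKR13KK, with a median of 13726 UMIs per cell. Summed UMIs weigh such deep cells more. Whether their share moved the proliferation list was not tested. Of 4577 genes edgeR passed 0, with 251 at an unadjusted p under 0.05, and DESeq2 passed 1. The granzyme Gzmf was at 1107 ± 1312 against 2.26 ± 0.188 CPM (log2 change 8.81 ± 1.25, adjusted p = 0.0977), and the change was 9.72 without LKR13KK 1 and 6.16 without LKR13KK 2. Its neighbour Gzmd was 0 in LKR13K and at 72.1 and 746 CPM in LKR13KK (adjusted p = 0.133). Gzmd, Gzme and Gzmf are close paralogs, so which of them a UMI came from is uncertain. Cd7, a T cell surface protein, was at 34.1 ± 10.1 against 153 ± 6.38 CPM (adjusted p = 0.0977). Sla2, an adaptor that dampens receptor signals, had a log2 change of −1.67 ± 0.29 (adjusted p = 0.163), and the growth factor gene Csf2 of 2.03 ± 0.34 (adjusted p = 0.148). Without LKR13K 1 edgeR passed 12 genes, and without LKR13KK 1, LKR13KK 2, LKR13KLK 1 or LKR13KLK 2 it passed 2, 1, 5 and 5. With the cells of both tumours pooled, cluster 7 held 41.3% of LKR13K T cells and 15.2% of those of LKR13KK, where cluster 5 held most (46.7%). The leading cluster differed between tumours of a group. Clusters 5 and 7 held 283 and 249 cells in LKR13K 1, but 104 and 204 in LKR13K 2. They held 156 and 41 cells in LKR13KK 1, and 13 and 14 in LKR13KK 2.

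In LKR13KK mononuclear phagocytes the list of conventional dendritic markers fell (0 of 3 above 0, median log2 change −0.77, adjusted p = 0.000337). Its member Ccl22, a chemokine that attracts regulatory T cells, passed when adjusted over the list alone. MHC class II genes, which present antigen to CD4 T cells, fell (0 of 8 above 0, median −0.49, adjusted p = 0.0392), with H2-DMb2 at −0.80, H2-Ab1 at −0.59 and Cd74 at −0.42. That call ended without LKR13K 1 (0.544) or LKR13KK 2 (0.275). Lipid handling genes fell by a median of −0.16 (4 of 13 above 0, adjusted p = 0.0137), with Apoe passing adjusted over the list alone, Gpnmb at −1.75 and Lipa at −0.60, until LKR13K 2 (0.514) or LKR13KK 2 (0.0590) was left out. Dissociation stress genes fell (1 of 15 above 0, median −0.32, adjusted p = 0.00964) and turned their direction without LKR13K 1 (0.777). Genes of the mitochondrial genome fell by a median of −0.15 (1 of 13 above 0, adjusted p = 0.0470), ending without LKR13K 1 (0.656), LKR13KK 1 (0.539) or LKR13KLK 2 (0.0625). All 5 lists had adjusted p between 0.920 and 0.947 with an estimated correlation.

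Single genes of LKR13KK phagocytes did not pass in edgeR (0 of 4085, with 115 at an unadjusted p under 0.05 and 5 by DESeq2). Apoe (7:19696109–19699188), a lipid carrier, was at 740 ± 84.1 against 2480 ± 85.3 CPM (log2 change −1.79 ± 0.28, adjusted p = 0.998, DESeq2 6.87e-05). Ccl22 was at 22.4 ± 4.25 against 148 ± 29.6 CPM (DESeq2 adjusted p = 0.0198). Tmem176b and Tmem176a, neighbouring membrane channel genes, had log2 changes of −2.14 ± 0.47 and −2.58 ± 0.59, and the growth factor Igf1 of −1.38 ± 0.32, each with adjusted p = 0.998. Without LKR13K 1 Tmem176b was at −1.39 and Tmem176a at −1.61, and without LKR13KK 1 Tmem176a was at −3.20. Pooled over tumours, cluster 2 held the most LKR13K phagocytes (31.6%) and cluster 0 the most LKR13KK ones (33.6%). The LKR13K tumours differed: clusters 2 and 0 held 161 and 89 cells in LKR13K 1, but 130 and 161 in LKR13K 2. In neutrophils edgeR passed 0 of 2781 genes (81 at an unadjusted p under 0.05, DESeq2 0), and no list was called. Sprr1a, a cornified envelope gene, was at 91.1 ± 56.2 CPM (11 and 20 UMIs) in LKR13K and 0 in LKR13KK neutrophils (adjusted p = 0.656). Hist2h2bb had 166 UMIs in LKR13KK 1 and 0 in LKR13KK 2 and LKR13K (adjusted p = 0.656), and Rnf144a (3.41 ± 0.85), Crip1 (−2.18 ± 0.58) and Anxa1 (−2.43 ± 0.64) had adjusted p = 0.999. Rnf144a was at 2.82 without LKR13KK 1 and Anxa1 at −1.79 without LKR13K 1. Without LKR13KK 2 edgeR passed 1 gene.

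The second comparison, LKR13KLK against LKR13K, asked how the cells read differ in tumours that lack both KEAP1 and LKB1. Plasma cells fell from 2.57% ± 1.49 to 0.0406% ± 0.0574, with odds 27.6-fold lower (adjusted p = 0.00301). Mast cells or basophils, granule cells of allergic responses, fell from 0.953% ± 0.493 to 0 in both tumours (adjusted p = 0.00322). The counts were 0 of 1232 and 0 of 781 cells, which allow shares of up to 0.244% and 0.384%. T cells were 34.9% ± 5.99 against 8.54% ± 5.02 and fibroblasts 7.30% ± 2.08 against 29.1% ± 3.04, both with no overlap between tumours and adjusted p = 0.0514. NK cells were 3.16% ± 1.37 against 0.893% ± 1.26 and conventional dendritic cells 2.61% ± 0.804 against 0.639% ± 0.360, both with adjusted p = 0.0915. Plasmacytoid dendritic cells were 2.11% ± 0.305 against 0.639% ± 0.360 (adjusted p = 0.144), and the other 5 classes had adjusted p between 0.171 and 0.689. Without LKR13K 1 the plasma cell call (0.112) and the mast cell call (0.128) both ended, as both did on the arcsine scale. The mast cell call also ended among cells of at least 2000 UMIs (0.111). NK cells passed without LKR13KK 1 or LKR13KLK 1, and T cells without LKR13KLK 1. Without LKR13KLK 1 its group was LKR13KLK 2 alone, which held 0 NK cells of 781, so that NK result rests on 1 tumour at 0.

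Fibroblasts of LKR13KLK tumours differed from those of LKR13K in 6 of 4520 genes by edgeR, 4 higher and 2 lower, with 496 at an unadjusted p under 0.05 and 85 by DESeq2. Gzme rose from 12.3 ± 2.26 to 106 ± 9.57 CPM (log2 change 3.13 ± 0.23, adjusted p = 0.00575). Mcpt1 (14:56017971–56020384), a mast cell protease, rose from 3.26 ± 3.81 to 157 ± 20.7 CPM (5.67 ± 0.54, adjusted p = 0.0153). With only 1 and 9 UMIs in the LKR13K tumours, its log2 change was 4.76 without LKR13K 1 and 8.02 without LKR13K 2. Ifitm1 rose from 32.5 ± 10.1 to 297 ± 25.6 CPM (3.21 ± 0.27, adjusted p = 0.00917). Olfr810 (10:129787289–129794917), annotated as an olfactory receptor, rose from 12.5 ± 5.72 to 75.8 ± 3.76 CPM (2.63 ± 0.31, adjusted p = 0.0391). Col8a1 fell from 718 ± 51.2 to 101 ± 2.19 CPM (−2.82 ± 0.18, adjusted p = 0.00422). Igkc (6:70726435–70726966) fell from 271 ± 124 CPM to 0, at least 734-fold (adjusted p = 0.0195, DESeq2 0.222), or at least 484-fold without LKR13K 1 and 221-fold without LKR13KLK 1, and 902 of its 914 UMIs in LKR13K lay in 2 cells. Gzme, Ifitm1 and Col8a1 passed whichever tumour was left out. Mcpt1 was lost without LKR13KLK 1 (0.0533) or LKR13KLK 2 (0.0623), and Igkc without LKR13KLK 1 (0.0766). Olfr810 was lost without LKR13KK 1 (0.0825), LKR13KK 2 (0.0799), LKR13KLK 1 (0.174) or LKR13KLK 2 (0.214). The count rose to 23 genes without LKR13K 1 and 12 without LKR13K 2, and was 0 when cells with markers of another class were left out.

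**Figure D2:**
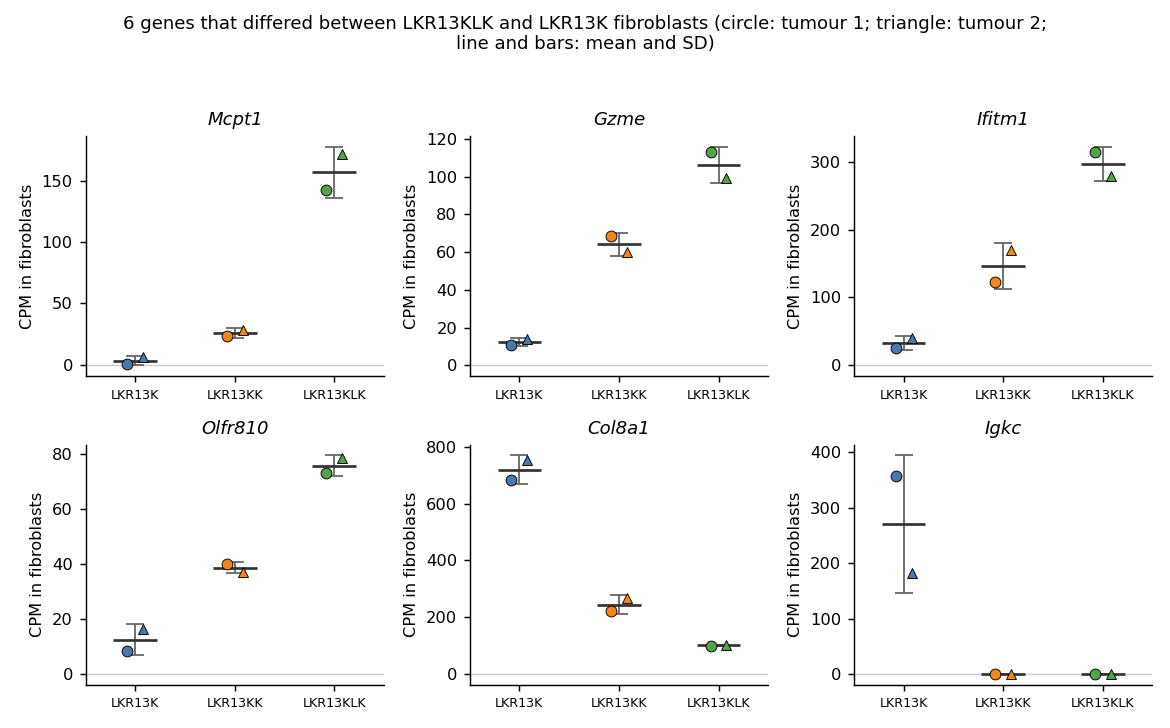
CPM in fibroblasts of each tumour for the 6 genes that differed between LKR13KLK and LKR13K, with the mean and SD of 2 tumours. Mcpt1, Gzme, Ifitm1 and Olfr810 lie higher in both LKR13KLK tumours, Col8a1 lies lower, and Igkc is 0 in every LKR13KK and LKR13KLK tumour.

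**Figure D3:**
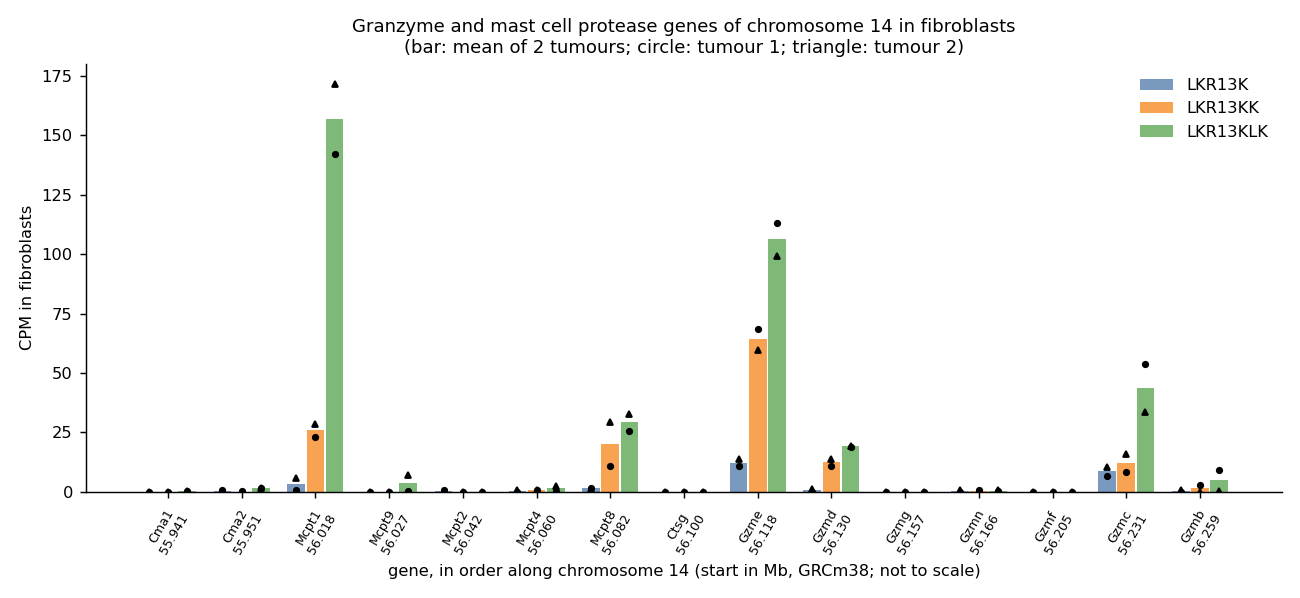
CPM in fibroblasts for granzyme and mast cell protease genes in their order along chromosome 14, with bars for the mean of 2 tumours and points for tumours. Mcpt1 and Gzme step up from LKR13K to LKR13KK to LKR13KLK, while Ctsg, Gzmg and Gzmf stay at 0.

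By groups, LKR13KLK fibroblasts had lower inflammatory cytokines (1 of 7 above 0, median log2 change −0.73, adjusted p = 0.00918). Il6, a cytokine of inflammatory fibroblasts, was at −1.90 ± 0.47 and passed adjusted over the list alone, with Ccl2 at −0.76 and Cxcl1 at −0.45. The call ended without LKR13K 2 (0.180) or LKR13KLK 2 (0.351). Inflammatory fibroblast genes fell by a median of −0.48 (1 of 12 above 0, adjusted p = 0.0126), with Il6 and Lif (−1.26) passing adjusted over the list alone, until LKR13K 1 (0.283) or LKR13KLK 2 (0.178) was left out. Markers of other cells moved beside them. Endothelial markers fell (0 of 3 above 0, median −1.83, adjusted p = 0.00702), with Flt1, Eng and Plvap passing adjusted over the list alone, ending without LKR13K 1 (0.0502). Pericyte markers fell (0 of 4 above 0, median −0.89, adjusted p = 0.0496), ending without LKR13K 2 (0.149) or LKR13KLK 1 (0.134). Ribosomal protein genes rose by a median of 0.22 (58 of 81 above 0, adjusted p = 0.0315), ending without LKR13K 1 (0.0891), LKR13K 2 (0.355) or LKR13KLK 2 (0.931). None of these members passed over all genes, and the 5 lists had adjusted p between 0.920 and 0.959 with an estimated correlation.

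LKR13KLK T cells had lower cytotoxicity genes as a group (2 of 12 above 0, median log2 change −0.83, adjusted p = 0.000276), with the chemokine Ccl5 at −3.02, Gzmk at −1.41 and the death ligand Fasl at −1.11. The granzymes Gzmf (4.43) and Gzmc (3.31) went the other way and passed adjusted over the list alone, but only LKR13KLK 1 was higher. Gzmf had 74 UMIs there and 0 in LKR13KLK 2, and Gzmc was at 496 and 11.02 CPM, against 31.8 and 21.8 in LKR13K. Inhibitory receptors and their regulators fell by a median of −0.65 (2 of 11 above 0, adjusted p = 0.00439), with Nr4a1 at −1.38, Tox at −1.03 and Lag3 at −0.98. Naive and memory genes rose by a median of 0.30 (7 of 8 above 0, adjusted p = 0.00828), with the transcription factors Klf2 at 2.34 and Lef1 at 1.82. Regulatory T genes fell by a median of −0.32 (3 of 9 above 0, adjusted p = 0.0271), with Ikzf2 passing adjusted over the list alone. NK markers fell by a median of −0.47 (0 of 4 above 0, adjusted p = 0.0273). LKR13KLK 2, with 39 T cells, carried all 5 calls: without it they ended at 0.524, 0.264, 0.807 with the direction turned, 0.876 and 0.573. The naive and memory call also ended without LKR13K 2 (0.0585), the regulatory T call without LKR13K 1 (0.207) and the NK marker call without LKR13K 2 (0.0602). Each list had adjusted p = 0.920 with an estimated correlation, and no member passed over all genes. EdgeR passed 0 of 4577 genes, with 296 at an unadjusted p under 0.05 and 4 by DESeq2.

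Among single genes of LKR13KLK T cells, the receptor segments Trbv14 and Trbv12-1 were 0 in LKR13KLK, with 730 and 259, and 169 and 325 UMIs in the LKR13K tumours. LKR13KLK 2 gave few T cell UMIs, so a 0 there says little. Itgae, an integrin of tissue-resident T cells, was at 9.56 ± 2.06 against 62.7 ± 20.3 CPM (log2 change −3.09 ± 0.59, −2.39 without LKR13KLK 1). Gzme was 0 in LKR13K and LKR13KLK 2 and had 192 UMIs in LKR13KLK 1. B4galnt4 was at −2.39 ± 0.47, or −9.71 without LKR13KLK 1, since LKR13KLK 2 had 0. These 5 genes had adjusted p = 0.450, and Trbv segments resemble each other closely enough that their assignment is uncertain. Without LKR13K 1, LKR13KK 1, LKR13KK 2 or LKR13KLK 1 edgeR passed 11, 1, 1 and 5 genes. Pooled over tumours, cluster 7 held the most LKR13K T cells (41.3%) and cluster 5 the most LKR13KLK ones (47.9%). In LKR13K 1 cluster 5 led with 283 cells against 249, and in LKR13K 2 cluster 7 led with 204 against 104. Clusters 5 and 7 held 54 and 47 cells in LKR13KLK 1, and 36 and 1 in LKR13KLK 2.

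LKR13KLK mononuclear phagocytes had lower lipid handling genes (3 of 13 above 0, median log2 change −0.38, adjusted p = 0.00242), with Apoe passing adjusted over the list alone, the glycoprotein Gpnmb at −1.98 and the lysosomal lipase Lipa at −0.77. The call ended without LKR13K 2 (0.182) or LKR13KLK 1 (0.128). Tumour-associated macrophage genes fell by a median of −0.11 (8 of 20 above 0, adjusted p = 0.0273), with Gpnmb at −1.98 and Mmp12 at −1.01 but the scavenger receptor Cd163 at 1.61, ending without LKR13K 1 (0.164) or LKR13KLK 1 (0.343). Apoe passed adjusted over this list alone as well. MHC class II genes fell by a median of −0.51 (1 of 8 above 0, adjusted p = 0.0287), with H2-Ab1 at −0.70, H2-Aa at −0.66 and Cd74 at −0.61. That call ended without LKR13K 1 (0.441) and turned its direction without LKR13KLK 2 (0.606). Conventional dendritic markers fell by a median of −0.56 (1 of 3 above 0, adjusted p = 0.0150), with 1 member lower adjusted over the list alone, ending without LKR13K 1 (0.246) or LKR13KLK 2 (0.531). Neutrophil markers rose by a median of 1.11 (4 of 5 above 0, adjusted p = 0.0484), ending without LKR13K 1 (0.167) or LKR13K 2 (0.180) and turning without LKR13KLK 1 (0.807). Dissociation stress genes fell by a median of −0.33 (2 of 15 above 0, adjusted p = 0.0463), turning without LKR13K 1 (0.647) and ending without LKR13KLK 1 (0.491). All 6 lists had adjusted p = 0.920 with an estimated correlation.

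No single gene of these phagocytes passed in edgeR (0 of 4085, 189 at an unadjusted p under 0.05, DESeq2 10). Tent5c, a poly(A) polymerase, was at 8.25 ± 2.36 against 47.6 ± 3.997 CPM (log2 change −2.47 ± 0.33, adjusted p = 0.837, DESeq2 0.000156). Cxcr4, a chemokine receptor, was at −1.88 ± 0.29 (adjusted p = 0.913). The cytokine Il18 (1.93 ± 0.35), the cyclin Ccnd2 (1.95 ± 0.39) and Apoe (−1.46 ± 0.27) had adjusted p = 0.9753, with Ccnd2 at 1.33 without LKR13KLK 1. DESeq2 gave Cxcr4, Il18, Apoe and Ccnd2 adjusted p of 0.000981, 0.00339, 0.00339 and 0.0199. Without LKR13K 1 edgeR passed 5 genes. Pooled over tumours, cluster 2 held the most LKR13K phagocytes (31.6%) and cluster 0 the most LKR13KLK ones (34.3%). In LKR13K 2, however, cluster 0 led with 161 cells against 130 in cluster 2. In LKR13KLK 1 cluster 4 led with 178 cells against 155 in cluster 0.

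In LKR13KLK neutrophils, a class added after the data were seen, edgeR passed 1 of 2781 genes and the limma test chosen beforehand passed 0. DESeq2 passed 2, and 177 genes had an unadjusted p under 0.05 in edgeR. Ccn3 (15:54745702–54754039), a matricellular protein, was 0 in LKR13K and 182 ± 117 CPM in LKR13KLK, at least 21.6-fold higher (adjusted p = 0.0373). Its UMIs numbered 18 and 42 in the LKR13KLK tumours, and the call ended without LKR13K 1 (0.249), LKR13K 2 (0.140) or LKR13KLK 2 (0.537). The lower limit of its fold was 9 without LKR13K 1, 12.6 without LKR13K 2 and 12.2 without LKR13KLK 2, and 32.4 without LKR13KLK 1 (still a call). Rnd1 (2.72 ± 0.55, adjusted p = 0.317), Sprr1a (11 and 20 UMIs in LKR13K, 0 in LKR13KLK, 0.375), Rrm2 (53 and 3 UMIs in LKR13K, 0 in LKR13KLK, 0.560) and Cxcr4 (−1.82 ± 0.45, 0.560) followed. NRF2 targets fell (3 of 14 above 0, median log2 change −0.63, adjusted p = 0.0102), with the glutathione genes Gsr (−2.42, 1 member lower adjusted over the list alone) and Gclm (−2.12), Tkt at −1.69, and the ferritin gene Fth1 at 0.54. The call ended without LKR13K 2 (0.220) or LKR13KLK 2 (0.0885). Glycolysis and hypoxia genes fell by a median of −0.38 (2 of 21 above 0, adjusted p = 0.00777), with Gapdh at −1.74 ± 0.47 passing adjusted over the list alone and Pgk1 at −1.06, ending without LKR13K 1 (0.350) or LKR13KLK 1 (0.182). RNA quality lists moved beside them: ribosomal protein genes fell by a median of −0.69 (9 of 80 above 0, adjusted p = 2.36e-10), ending without LKR13K 1 (0.221). Genes of the mitochondrial genome fell by a median of −0.50 (0 of 12 above 0, adjusted p = 0.00211), ending without LKR13K 1 (0.0502) or LKR13KLK 1 (0.619). Dissociation stress genes rose by a median of 0.46 (12 of 15 above 0, adjusted p = 0.0302), turning without LKR13K 2 (0.946) and ending without LKR13KK 2 (0.0514) or LKR13KLK 2 (0.310). The 5 lists had adjusted p between 0.920 and 0.947 with an estimated correlation.

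The third comparison, LKR13KLK against LKR13KK, asked what differs between tumours lacking KEAP1 alone and those lacking LKB1 as well. Mast cells or basophils fell from 1.03% ± 0.828 in LKR13KK to 0 of 1232 and 0 of 781 cells in LKR13KLK (adjusted p = 0.00322). The call ended without LKR13KK 1 (0.0990), on the arcsine scale (0.141) and among cells of at least 2000 UMIs (0.0616). Fibroblasts were 17.7% ± 5.09 against 29.1% ± 3.04 (adjusted p = 0.417), mononuclear phagocytes 51.3% ± 3.43 against 38.1% ± 6.32 and neutrophils 8.31% ± 1.99 against 13.9% ± 6.73 (both 0.475). B cells and NK cells had adjusted p = 0.186, and T cells (10.3% ± 6.33 against 8.54% ± 5.02) 0.833, as did plasma cells. B cells passed without LKR13KK 1 or LKR13KLK 1, and NK cells without LKR13KLK 1. Each of these fits left 1 tumour in a group. LKR13KK 2 alone held 0 B cells of 681, and LKR13KLK 2 alone held 0 NK cells of 781. The other classes had adjusted p between 0.475 and 0.988.

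Fibroblasts of these groups differed in 0 of 4520 genes by edgeR, with 172 at an unadjusted p under 0.05 and 14 by DESeq2. Col8a1 (log2 change −1.31 ± 0.17), Mcpt1 (2.58 ± 0.39), the contractile gene Tagln (−1.40 ± 0.21), Ccn3 (−1.48 ± 0.23) and the secreted phosphoprotein Spp1 (−1.36 ± 0.22) had adjusted p = 0.334. Tagln was at 308 ± 58.8 against 792 ± 85.6 CPM, and Spp1 at 3921 ± 956 against 9737 ± 1622 CPM. DESeq2 passed all 5, with adjusted p from 7.93e-10 for Mcpt1 to 0.00136 for Ccn3. The lists of this comparison that follow for fibroblasts each had adjusted p = 0.920 with an estimated correlation. Interferon response genes fell as a group (2 of 12 above 0, median −0.55, adjusted p = 0.00184), with the chemokine Cxcl10 at −2.003, Iigp1 at −1.69 and Isg15 at −0.59, ending without LKR13KK 1 (0.525) or LKR13KLK 2 (0.984). MHC class I genes fell by a median of −0.52 (0 of 11 above 0, adjusted p = 0.00246) and turned without LKR13KK 1 (0.992) and without LKR13KLK 2 (0.570). Glycolysis and hypoxia genes fell by a median of −0.22 (3 of 21 above 0, adjusted p = 0.00179), turning without LKR13KK 1 (0.537) and ending without LKR13KLK 2 (0.310). Extracellular matrix genes fell by a median of −0.17 (5 of 17 above 0, adjusted p = 0.00980), with Tagln passing adjusted over the list alone, Acta2 at −1.02 and Thbs1 at −0.45, ending without LKR13KK 1 (0.373) or LKR13KLK 1 (0.0685).

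Inflammatory fibroblast genes of LKR13KLK fell against LKR13KK by a median log2 change of −0.32 (0 of 12 above 0, adjusted p = 0.0124), turning without LKR13KK 1 (0.169) and ending without LKR13KLK 2 (0.264). Dissociation stress genes rose in these fibroblasts (15 of 15 above 0, median 0.33, adjusted p = 0.0188), ending without LKR13KK 2 (0.0514) or LKR13KLK 2 (0.814). Endothelial markers fell by a median of −0.80 (0 of 3 above 0, adjusted p = 0.000850), with 2 members lower adjusted over the list alone, whichever tumour was left out. Tumour-associated macrophage genes fell by a median of −0.25 (2 of 6 above 0, adjusted p = 0.0436), with Spp1 passing adjusted over the list alone. That call ended without LKR13K 1 (0.0891), LKR13K 2 (0.0743), LKR13KK 1 (0.179), LKR13KLK 1 (0.0655) or LKR13KLK 2 (0.169). All 8 fibroblast lists had adjusted p = 0.920 with an estimated correlation.

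Cytotoxicity genes were lower as a group in LKR13KLK than in LKR13KK T cells (1 of 12 above 0, median log2 change −0.76, adjusted p = 6.32e-10), ending without LKR13KLK 2 (0.0792). Interferon gamma (Ifng, −2.62 ± 0.44), Gzmf (−4.38) and Gzmb (−1.66) were lower adjusted over the list alone. In the same cells glycolysis and hypoxia genes fell by a median of −0.62 (1 of 16 above 0, adjusted p = 2.79e-07) whichever tumour was left out, and the mitophagy gene Bnip3 (−2.28 ± 0.48) passed adjusted over the list alone. Proliferation genes fell by a median of −0.49 (3 of 16 above 0, adjusted p = 1.42e-06), with Top2a at −0.99, ending without LKR13KLK 2 (0.351). Naive and memory genes rose by a median of 0.55 (6 of 8 above 0, adjusted p = 0.00777), ending without LKR13KK 2 (0.149) and turning without LKR13KLK 2 (0.524). Regulatory T genes (0 of 9 above 0, adjusted p = 0.0150) and inhibitory receptors (2 of 11 above 0, adjusted p = 0.0189, 1 member lower adjusted over the list alone) each fell by a median of −0.29. Without LKR13KK 1 these calls ended at 0.868 and 0.136, and without LKR13KLK 2 at 0.814 and 0.538. Dissociation stress genes rose by a median of 0.44 (8 of 11 above 0, adjusted p = 0.0302), ending without LKR13KK 2 (0.252) or LKR13KLK 2 (0.566). Tumour-associated macrophage genes fell by a median of −1.02 (0 of 3 above 0, adjusted p = 0.0450), ending without LKR13KK 2 (0.110), LKR13KLK 1 (0.0888) or LKR13KLK 2 (0.241). All 8 T cell lists had adjusted p = 0.920 with an estimated correlation.

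Single T cell genes passed in none of 4577 tests of edgeR in this comparison (0, with 94 at an unadjusted p under 0.05 and 2 by DESeq2). Ifng was at 18.2 ± 25.8 against 171 ± 12.4 CPM (adjusted p = 0.317), and −11.13 on the log2 scale without LKR13KLK 1, as LKR13KLK 2 had 0. Trbv14 was 0 in LKR13KLK and had 216 and 117 UMIs in LKR13KK (0.317). Ifitm2 (−1.95 ± 0.40), Ifitm1 (−4.84 ± 1.01) and Bnip3 had adjusted p = 0.725. Ifitm1 leaned on single tumours, at −5.715 without LKR13KK 1, −2.69 without LKR13KK 2 and −13.49 without LKR13KLK 1, and Bnip3 was at −1.45 without LKR13KK 1. Without LKR13KLK 1 edgeR passed 5 genes, without LKR13KK 1 it passed 1, and without LKR13K 1, LKR13K 2 or LKR13KK 2 it passed 2 each.

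Mononuclear phagocytes of LKR13KLK had lower MHC class I genes than those of LKR13KK (0 of 12 above 0, median log2 change −0.26, adjusted p = 0.00167), ending without LKR13KK 1 (0.662) and turning upward past the threshold without LKR13KLK 2 (0.0272). Tumour-associated macrophage genes fell by a median of −0.28 (5 of 20 above 0, adjusted p = 0.00391), with Spp1 at −1.40 and Mmp12 at −0.81 but Chil3 at 2.28 and Cd163 at 1.31, ending without LKR13KK 1 (0.0544) or LKR13KLK 1 (0.408). Genes of glycolysis and hypoxia fell by a median of −0.16 (3 of 20 above 0, adjusted p = 0.0271) and turned without LKR13KK 1 (0.645) and without LKR13KLK 2 (0.911). No member passed over all genes or adjusted over the list alone, and the lists had adjusted p between 0.920 and 0.945 with an estimated correlation. EdgeR passed 0 of 4085 genes, with 22 at an unadjusted p under 0.05 and 0 by DESeq2. The smallest p belonged to Tent5c (−1.39 ± 0.33), the chemokine Ccl24 (−1.98 ± 0.56), the leukotriene synthase Ltc4s (2.07 ± 0.60), Igf1 (1.11 ± 0.32) and Ms4a7 (−1.09 ± 0.33), all with adjusted p = 1. Ccl24 was at −0.78 without LKR13KK 1 and −2.62 without LKR13KK 2, and Ltc4s at 2.81 without LKR13KK 2 and 1.36 without LKR13KLK 2.

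LKR13KLK neutrophils had lower NRF2 targets than LKR13KK neutrophils (3 of 14 above 0, median log2 change −0.86, adjusted p = 0.000628) whichever tumour was left out, with Gclm at −2.74, Pgd at −1.74, Gsr at −1.68 and the heme oxygenase Hmox1 at −1.15. Glycolysis and hypoxia genes fell by a median of −0.42 (2 of 21 above 0, adjusted p = 0.00201), with Gapdh at −1.51, Eno1 at −1.24 and Pgk1 at −1.13, ending without LKR13KK 2 (0.363) or LKR13KLK 1 (0.117). MHC class I genes fell by a median of −0.51 (1 of 12 above 0, adjusted p = 0.0273), turning without LKR13KK 1 (0.580) and ending without LKR13KLK 2 (0.653). The RNA quality lists moved with them. Ribosomal protein genes fell by a median of −0.62 (6 of 80 above 0, adjusted p = 1.82e-12) whichever tumour was left out, and genes of the mitochondrial genome by a median of −0.84 (0 of 12 above 0, adjusted p = 2.09e-05), ending without LKR13KLK 1 (0.248). No member passed over all genes or adjusted over the list alone, and the 5 lists had adjusted p = 0.920 with an estimated correlation. EdgeR passed 0 of 2781 genes, with 143 at an unadjusted p under 0.05 and 1 by DESeq2. Ccn3 (4.35 ± 0.82, adjusted p = 0.468), Hist2h2bb (166 and 0 UMIs in LKR13KK, 0 in LKR13KLK, 0.654), Efr3b (74 and 0 UMIs in LKR13KK, 0 in LKR13KLK, 0.723), BC100530 (−5.98 ± 1.52, 0.900) and 1 predicted gene had the smallest p. Ccn3 was at 7.81 without LKR13KK 1 and 3.62 without LKR13KLK 2. BC100530 was at −3.45 without LKR13KK 1, −6.78 without LKR13KK 2, −4.998 without LKR13KLK 1 and −10.74 without LKR13KLK 2. Without LKR13KK 2 edgeR passed 3 genes.

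Within the T and NK cells of all groups, no subset share passed (adjusted p from 0.654 to 0.840). CD8 T cells, the killer lineage, were 50.6% ± 6.13 in LKR13K, 35.5% ± 13.1 in LKR13KK and 22.6% ± 28.4 in LKR13KLK. Regulatory T cells were 16.0% ± 1.14, 18.6% ± 5.28 and 11.9% ± 9.61, other CD4 T cells 14.6% ± 0.143, 18.2% ± 4.74 and 12.2% ± 10.0, and gamma-delta T cells 1.29% ± 1.501, 2.35% ± 0.313 and 2.74% ± 0.255. NK cells were 9.05% ± 2.73, 14.3% ± 5.20 and 6.73% ± 9.51 of these cells. Subclusters with no name held 33 of the 39 T and NK cells of LKR13KLK 2 (84.6%), against 2.92% to 12.8% in the other tumours. Different subclusters made up the CD8 cells: subcluster 0 held 60.03% of them in LKR13K but 2.44% in LKR13KK and 5.41% in LKR13KLK, where subcluster 6 led with 43.1% and 52.7%. Without LKR13KLK 1 the CD8 share passed against LKR13K (adjusted p = 0.00743) and LKR13KK (0.0125), and the NK share did so too (0.0375 and 0.0125), which rests on LKR13KLK 2 with most of its cells unnamed.

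Lists that were called in no class or comparison were checkpoint ligands (lowest adjusted p = 0.365), epithelial markers (0.328), mononuclear phagocyte markers (0.152), neutrophil activation (0.131) and oxidative phosphorylation (0.170). Of the 228 list tests 56 were called, 12 upward and 44 downward, 6 held whichever tumour was left out, and 0 with an estimated correlation (adjusted p from 0.920 to 0.959).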

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

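With 2 tumours per group, many results lean on single tumours, and the exact permutation p of 2 against 2 cannot go below 0.3333. When 1 tumour is left out, its group keeps 1 tumour, which is assumed to vary like those of the other groups. In simulated data the edgeR test recovered 2.99% to 44.8% of genes changed 2-fold, 41.8% to 98.5% of those changed 4-fold and 78.8% to 100% of those changed 8-fold, with 4.97% to 11.7% of calls false, so a count of 0 does not exclude 2-fold changes. The simulated list had camera p from 7.22e-09 to 0.0223. Each simulated gene was drawn independently and 200 were changed, so neither the recovery nor the list p carries over directly to these data. Ccl22 in LKR13KK phagocytes, 6.68-fold lower than in LKR13K, had an edgeR adjusted p of 0.998. A count of 0 therefore does not exclude larger changes either. DESeq2 and its size factors, the fit with no TMM factors, bias-adjusted quasi-dispersions, gene symbols as deposited, the limit of 2000 UMIs per cell, the T cell and neutrophil classes and 3 settings for subsets were added after the data were seen. Summed UMIs, planned as an alternative, became the main test, and robust empirical Bayes was run in edgeR instead of limma. Dropping the TMM factors moved the median log2 change of all genes to 0.15 in LKR13KLK against LKR13K T cells, and to −0.13 and −0.11 in LKR13KK and LKR13KLK against LKR13K neutrophils. Wherever a setting moved a result, the cause was not tested.

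Over 36 class shares, 459 alternatives gave the same call in 401 cases, a stronger one in 28, a weaker one in 11 and the other direction in 19. Over 15 subset shares, 195 alternatives left 171 calls the same. Of 336 alternatives for gene counts 95 moved the count, and of 504 alternatives for called lists 141 weakened and 16 turned the call. Of 1633 alternatives for named genes 1454 left the call the same.

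Class shares moved as follows. Arcsine values gave adjusted p = 0.0285 for mononuclear phagocytes, 0.0571 for plasma cells, 0.00932 for T cells and 0.986 for mast cells, now in the other direction, in LKR13KK against LKR13K. For LKR13KLK against LKR13K they gave 0.00511 for fibroblasts, 0.00731 for T cells, 0.0566 for plasma cells and 0.141 for mast cells, and mast cells had 0.141 against LKR13KK as well. With 2 groups only, B cells reached 0.00384 in LKR13KK against LKR13K and natural killer cells 0.0435 in LKR13KLK against LKR13K. Coarser clusters gave 0.0434 for B cells and conventional dendritic cells in LKR13KK and for fibroblasts and T cells in LKR13KLK, each against LKR13K. Among cells of at least 2000 UMIs, mast cells and neutrophils of LKR13KK turned their direction against LKR13K (0.671 each), and the mast cell calls of LKR13KLK ended at 0.111 against LKR13K and 0.0616 against LKR13KK. Among immune cells only, mast cells of LKR13KK turned their direction against LKR13K (0.844).

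Subset shares of T and NK cells moved in other settings. Finer clusters gave the CD8 T share adjusted p = 0.0145 in both LKR13KK and LKR13KLK against LKR13K, and turned gamma-delta T cells of LKR13KLK against LKR13KK (0.698). The lower CD8 share came with a change of names: of the CD8 T cells at the main resolution, finer clusters named 15.5% natural killer cells in LKR13K, 65.9% in LKR13KK and 77.03% in LKR13KLK. Both finer clusters that took them had 0 natural killer markers among their leading 10 genes, so these values are no evidence of fewer CD8 T cells. Coarser clusters turned other CD4 T cells in LKR13KLK against LKR13K (0.757) and gamma-delta T cells in LKR13KLK against LKR13KK (0.976). With a denominator of all cells, gamma-delta T cells turned in all 3 comparisons (0.964 each), as did natural killer cells, other CD4 T and regulatory T cells in LKR13KK against LKR13K (0.690 each). Among cells of at least 2000 UMIs other CD4 T and regulatory T cells of LKR13KLK turned against LKR13K (0.982 each).

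A replicate block paired tumours by number. It gave class shares adjusted p = 0.0399 for conventional dendritic cells and pericytes, 0.0434 for fibroblasts and 0.0229 for T cells in LKR13KK against LKR13K. For LKR13KLK against LKR13K it gave 0.0181 for fibroblasts and T cells and 0.0399 for pericytes and plasmacytoid dendritic cells. Under the block 9 fibroblast genes passed in LKR13KK against LKR13K, 11 in LKR13KLK against LKR13K (6 shared), and 1 neutrophil gene in LKR13KLK against LKR13KK. Of the genes that passed in edgeR, Ccn3 in neutrophils of LKR13KLK against LKR13K was lost under the block (0.0806). Lists called numbered 5 for phagocytes of LKR13KLK against LKR13KK (3 shared) and 8 for neutrophils of LKR13KLK against LKR13K (5 shared). Correlations between tumours of the same number in LKR13K and LKR13KK, LKR13K and LKR13KLK, and LKR13KK and LKR13KLK were 0.191, 0.194 and 0.658 in phagocytes and 0.0018, −0.0212 and 0.414 in fibroblasts. They were 0.0741, −0.1255 and −0.0742 in T cells, and 0.102, −0.058 and 0.0775 in neutrophils. All 3 lay over 0.1 in phagocytes alone. The labels tie no number to a litter, batch or day, and each group has only 2 tumours, so the numbers were not taken to pair tumours. Of the 56 list calls 53 passed under the block. The others, all in phagocytes, were the mitochondrial genome in LKR13KK against LKR13K (0.0665), and dissociation stress (0.0724) and neutrophil markers (0.158) in LKR13KLK against LKR13K.

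Counts of genes differing moved with the tool and filter, given for LKR13KK against LKR13K, LKR13KLK against LKR13K and LKR13KLK against LKR13KK in turn. DESeq2 gave 5, 10 and 0 in phagocytes, 25, 85 (5 shared) and 14 in fibroblasts, 1, 4 and 2 in T cells, and 0, 2 (1 shared) and 1 in neutrophils. With no filter the counts were 107, 148 and 18 in phagocytes, 215, 400 (6 shared) and 190 in fibroblasts, 135, 140 and 40 in T cells, and 8, 14 (1 shared) and 11 in neutrophils. No filter with bias-adjusted quasi-dispersions gave 18 and 42 (6 shared) in fibroblasts for the first pair of comparisons, 10, 5 and 1 in T cells, and 10, 16 (1 shared) and 12 in neutrophils. Genes of at least 100 CPM left 2 in fibroblasts (2 shared) and 0 in neutrophils for LKR13KLK against LKR13K.

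In fibroblasts the count of genes for LKR13KK against LKR13K, 0 by edgeR, became 1 with 2 groups only, without doublet-marker cells, without a trend in limma, with the mean of log values, with pseudocounts of 5 and 20, with quantile normalization and with median centring. It became 2 with no TMM factors and 3 with robust empirical Bayes. For LKR13KLK against LKR13K, 6 by edgeR, fibroblasts had 10 with 2 groups only (5 shared), 0 without doublet-marker cells, 3 with symbols as deposited (3 shared), 10 with the mean of log values (4 shared), 11 with a pseudocount of 1 (5 shared), 12 with pseudocounts of 5 and 20 (6 shared) and 14 with quantile normalization (6 shared). The neutrophil count for LKR13KLK against LKR13K, 1 by edgeR, became 0 with symbols as deposited, without a trend in limma, with pseudocounts of 1, 5 and 20, with quantile normalization and with no TMM factors. It became 3 with the mean of log values (0 shared), which also gave 1 for LKR13KK against LKR13K. Among cells of at least 2000 UMIs neutrophils had 1, 2 (0 shared) and 7 genes, and without doublet-marker cells 1 for LKR13KLK against LKR13KK. T cells had 1 gene for LKR13KLK against LKR13K and 2 for LKR13KLK against LKR13KK with 2 groups only, and 1 for each without doublet-marker cells.

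With an estimated correlation the lists called fell to 0 in every class and comparison. They had numbered 5, 6 and 3 in phagocytes, 3, 5 and 8 in fibroblasts, and 3, 5 and 8 in T cells. The neutrophil comparisons with LKR13KLK had 5 each. Tumour-associated macrophage genes in phagocytes of LKR13KLK against LKR13K had an estimated correlation of 0.0141, near the preset 0.01. Even so, their camera p went from 0.00518 to 0.0732. For a list with such a low estimate, not passing in the estimated form therefore neither upholds nor undoes the call. Other estimates were far higher. The 5 lists called in phagocytes of LKR13KK against LKR13K had estimates from 0.172 (lipid handling) to 0.880 (MHC class II). The camera p of MHC class II there went from 0.00859 to 0.384. Where genes of a list are that correlated, the preset form gives too small a p, so such calls may be overstated.

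Leaving out each tumour gave these ranges of adjusted p for class shares. In LKR13KK against LKR13K they were 0.000910 to 0.125 for plasma cells, 0.698 to 0.990 for mast cells, 0.853 to 0.990 for neutrophils, 0.00230 to 0.385 for B cells and 0.488 to 0.983 for natural killer cells. In LKR13KLK against LKR13K they were 0.00105 to 0.112 for plasma cells, 0.00427 to 0.128 for mast cells, 0.0260 to 0.337 for T cells and 0.000910 to 0.734 for natural killer cells. In LKR13KLK against LKR13KK they were 0.00427 to 0.0990 for mast cells, 0.0120 to 0.781 for B cells, 0.853 to 0.977 for pericytes, 0.620 to 0.966 for plasma cells, 0.519 to 0.965 for T cells, 0.698 to 0.990 for conventional dendritic cells, 0.719 to 0.990 for endothelial cells and 0.00184 to 0.990 for natural killer cells.

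Leaving out each tumour gave subset shares 0.722 to 0.987 for regulatory T cells in LKR13KK against LKR13K. In LKR13KLK against LKR13K the ranges were 0.00743 to 0.987 for CD8 T, 0.0375 to 0.987 for natural killer cells, 0.260 to 0.987 for other CD4 T and 0.225 to 0.987 for regulatory T cells. In LKR13KLK against LKR13KK they were 0.0125 to 0.987 for CD8 T and natural killer cells, 0.165 to 0.987 for other CD4 T and 0.165 to 0.992 for regulatory T cells.

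Leaving out each tumour moved gene counts from 0 to 5 in phagocytes of LKR13KLK against LKR13K, and in fibroblasts from 0 to 12 for LKR13KK and 4 to 23 for LKR13KLK, both against LKR13K. In T cells they ranged from 0 to 12, 0 to 11 and 0 to 5 in the 3 comparisons in turn, and in neutrophils from 0 to 1, 0 to 1 and 0 to 3. Lists called ranged from 2 to 8, 1 to 7 and 4 to 9 in phagocytes, 1 to 7, 2 to 8 and 4 to 10 in fibroblasts, and 2 to 6, 4 to 11 and 4 to 12 in T cells. In neutrophils they ranged from 0 to 4 for LKR13KK and 3 to 6 for LKR13KLK, both against LKR13K.

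Among called lists, the ranges without 1 tumour that included the other direction were as follows. Dissociation stress ranged from 7.27e-07 to 0.777 in phagocytes of LKR13KK and from 5.22e-06 to 0.647 in those of LKR13KLK against LKR13K, and from 8.93e-07 to 0.946 in neutrophils of LKR13KLK against LKR13K. Glycolysis and hypoxia ranged from 4.20e-10 to 0.942 in fibroblasts of LKR13KK against LKR13K. Against LKR13KK, LKR13KLK ranged for that list from 0.000140 to 0.911 in phagocytes and 8.10e-10 to 0.537 in fibroblasts. MHC class I ranged in that comparison from 2.68e-13 to 0.662 in phagocytes, 3.64e-15 to 0.992 in fibroblasts and 3.16e-05 to 0.653 in neutrophils, and inflammatory fibroblast genes from 4.25e-10 to 0.264 in fibroblasts. In LKR13KLK against LKR13K phagocytes, MHC class II ranged from 3.22e-09 to 0.606 and neutrophil markers from 9.75e-05 to 0.807. Naive and memory T cell genes ranged from 4.60e-12 to 0.807 in LKR13KLK against LKR13K and from 1.49e-09 to 0.524 against LKR13KK.

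Among named genes, Gzme in T cells of LKR13KLK against LKR13K ranged from a log2 change of 0.0 without LKR13KLK 1 to 11.319. Hist2h2bb in neutrophils ranged from 0.0 without LKR13KK 1 to 9.801 in LKR13KK against LKR13K, and from −9.801 to 0.0 in LKR13KLK against LKR13KK. Efr3b in neutrophils of LKR13KLK against LKR13KK ranged from −8.638 to 0.0, again without LKR13KK 1.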

Other observations

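The annotation and depth tests of the clusters of LKR13K 2, and the tests of Mcpt1 without LKR13K 2 and of free Igkc RNA, were chosen only after the result was seen. The genotype test of those clusters was chosen before.

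Neighbouring protease genes of chromosome 14 (56017971 to 56262260) were read together in fibroblasts. Mcpt1 was at 0.563 and 5.95 CPM in LKR13K, 23.1 and 28.6 in LKR13KK, and 142 and 172 in LKR13KLK. Gzme followed the same order, with 10.7 and 13.9, 68.5 and 59.8, and 113 and 99.5 CPM. Gzmd went from 0 and 1.32 to 11.02 and 13.95 and to 18.9 and 19.3 CPM, and Mcpt8 from 1.69 and 1.32 to 10.8 and 29.2 and to 25.8 and 32.7 CPM. Ctsg, Gzmg and Gzmf, in the same stretch, were 0 in fibroblasts of every tumour, and Mcpt2, Mcpt4 and Gzmn reached at most 2.52 CPM. Mcpt9 (0.36 and 7.13 CPM) and Gzmb (9.37 and 0.42) differed between the LKR13KLK tumours. Gzmc was at 6.75 and 10.6 CPM in LKR13K, 8.27 and 15.9 in LKR13KK, and 53.7 and 33.6 in LKR13KLK, with no clear step in LKR13KK. The flanking gene Nfatc4 was also highest in LKR13KLK (48.5 and 49.9 CPM, against 17.2 to 36.001 in the others), by far less than Mcpt1. Nearer to Mcpt1, the flanking genes Nynrin, Khnyn and Sdr39u1 did not rise. In LKR13KLK Nynrin was at 7.93 and 7.97 CPM (3.99 to 8.59 in the others) and Khnyn at 15.5 and 7.97 (10.7 to 18.6). Sdr39u1 was at 6.67 and 4.62 CPM (4.23 to 11.3). Cma1 and Cma2, nearer still, reached at most 1.68 CPM. Within fibroblast cluster 3, which held most cells with Mcpt1, single cells with both Mcpt1 and Gzme numbered 26 in LKR13KLK 1, where 11.5 would be due if the genes were independent (Fisher exact p = 1.02e-07). They numbered 16 against 7.60 in LKR13KLK 2 (Fisher exact p = 0.000309). In LKR13KK 1 and 2 they numbered 10 against 3.74 and 8 against 4.25 (Fisher exact p = 0.000420 and 0.0290), in LKR13K 2 they numbered 2 against 0.506 (Fisher exact p = 0.0759), and in LKR13K 1 they numbered 0 against 0.08 (Fisher exact p = 1). Cell depth was not held fixed in these counts, and Gzmd, Gzme and the Mcpt genes are paralogs whose UMIs can be misassigned.

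Among CD8 T cells with a Trbv segment read, Trbv12-1 was found in 15.6% (95% interval 11.8 to 20.2) of those of LKR13K 1, 57.1% (50.02 to 63.99) of LKR13K 2 and 45.0% (34.6 to 55.9) of LKR13KK 1. Trbv14 was found in 25.6%, 19.05% and 13.8% of the same tumours. LKR13KK 2, with 15 such cells, had Trbv14 in 12 (95% interval 54.8% to 92.95%) and Trbv12-1 in 3 (7.05% to 45.2%). LKR13KLK 1 had 0 of 63 such cells with either segment, which allows a share of up to 4.76% from the sampling of cells alone. A cell can miss its own transcript, so this does not limit the share that uses a segment. LKR13KLK 2 had 1 CD8 T cell in all. Paired receptor chains were not read, so clones were not defined.

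Mcpt1 and Gzme in LKR13KLK fibroblasts were weighed against RNA from other cells. Mast cell genes (Cpa3, Mcpt4, Tpsb2, Cma1) gave 0.0117 UMIs per Mcpt1 UMI in fibroblasts (upper limit 0.0197) and 1.83 in the mast cell class. This argues against mast cells that carry these genes, or their free RNA. That class held 0 cells of either LKR13KLK tumour, so its ratio came from the other groups. Mcpt8, another marker of the class, was not in the ratio and had 143 and 78 UMIs in fibroblasts of LKR13KLK 1 and 2. Basophils were therefore not tested. Genes of NK and T cells (Nkg7, Gzmb, Il2rb) gave 0.0909 UMIs per Gzme UMI in fibroblasts of LKR13KLK 1 (upper limit 0.119) and 1.96 in its NK cells. This argues against NK cells as the main source of Gzme there. T cells of LKR13KLK 1 had 192 Gzme UMIs (195 CPM, against 113 in its fibroblasts) and were not tested as a source. LKR13KLK 2 held 0 NK cells. Its fibroblasts had 237 Gzme UMIs and 1 UMI of those genes, while its T cells had 0 and 72, which argues against T cells there. The annotation of LKR13K 2 was not needed, as the Mcpt1 log2 change was 8.019 without that tumour. One hypothesis is that fibroblasts, or malignant cells that resemble them, may transcribe some genes of this stretch of chromosome 14 themselves. Whether these cells are host fibroblasts stays open, since no knockout or sequence variant was read.

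Igkc in LKR13K fibroblasts was weighed against RNA of plasma cells, which were most frequent in that group. The fibroblast level was 25.5 times that of phagocytes in LKR13K 1 and 50.8 times in LKR13K 2, which argues against free RNA spread over all cells. The 11 fibroblasts with most Igkc held 100% of its UMIs, which was bound to happen, since only 10 had any. Of 219 fibroblasts, 2 held 902 of the 914 UMIs. Those 2 cells also had at least 68 UMIs of Col1a1 and 25 of Jchain, so plasma cells caught with fibroblasts are a likely source of this passing gene. No doublet caller was run, so this stays open.

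With symbols as deposited, 4 clusters came from LKR13K 2 alone and held 56.2% of its cells. Among symbols at 0 only in LKR13K 2, 123 paired with a symbol seen only there as names of the same gene, against 0 in each other tumour, which fits a different annotation. Merging these names alone left 2 such clusters with 438 cells, and leaving out the unpaired symbols too left 0. Those symbols were chosen because they set LKR13K 2 apart, so an effect of this tumour on the 2 clusters was left open. The genotype test could not tell, as 2 of the 4 clusters were left once names were merged. LKR13K 2 gave 254 of 255 and 183 of 183 cells of those 2 clusters. Clusters were counted only with over 95% of their cells from LKR13K 2, so these shares add no evidence on the genotype. LKR13K 1 has the same genotype and gave 1767 cells, so the genotype alone would not set LKR13K 2 apart. The lowest median depth among other tumours was 3561 UMIs per cell against 3707 in LKR13K 2, which argues against depth. Which annotation each tumour was counted with may only be settled by the submitters, and symbols lost in both forms stay unread.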
